A study of Sus scrofa with 6 samples.

How the data were processed

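RNA was measured in longissimus dorsi muscle of 6 female Tibetan pigs, 3 per group, and each library came from a separate animal per the labels. Per the labels' protocols, the muscle was frozen in liquid nitrogen at sampling, total RNA was extracted with TRIzol, and strand-specific libraries were made with the dUTP method and a TruSeq kit from Illumina. Per the submitters' processing notes, TopHat2 2.0.11 and Cufflinks 2.2.1 were used, with no role given. The genome build, the annotation release and any filters are not given in the sources used here, so no coordinates are printed. Time of day at sampling, feeding state and litter are not given either.

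The authors deposited FPKM values, fragments scaled to gene length and to the mapped total of the library, as 1 table of 25322 Ensembl pig gene IDs by 6 libraries, and columns were matched to animals by their titles. Symbols came from a table of gene IDs and names, which gave 11804 of the 25322 IDs a symbol and 6719 of the 10005 tested genes. A list symbol that had since been renamed was matched through 5 aliases. The deposited FPKM totals differ between libraries, so no further scaling to a common total had been applied. FPKM holds no counts, so no count model was used, absolute depth is unknown and no counting interval is given. Ratios of values under an FPKM of 0.15 between pairs of libraries clustered at a common value, from which relative depth was read. In 107 genes a library was listed at exactly 0 while another reached an FPKM of 5 or more, among them the skeletal muscle actin. A gene listed at 0 is therefore reported only as listed at 0. Genes that share sequence with close copies, such as ribosomal proteins, HSPA1L and myosin heavy chains, are uncertain because the way reads were divided between them is not stated.

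Values were analysed as log2(FPKM + 1), a pseudocount of 1. Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested with limma 3.58.1 in R 4.3.3, as low minus high altitude, with an empirical Bayes fit that follows the mean (trend), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. A further count asked for a change of at least 2-fold. The fold changes printed as folds are ratios of mean FPKM. The lists were tested against all other genes with limma's camera and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 25 lists with at least 5 tested members, and again with an estimated correlation and with fry. The size printed for a list is the mean log2 fold change of its members minus that of the other tested genes. Correlations between libraries were compared by an exact permutation test over the 10 splits of the 6 libraries. The steps were tested on simulated data made from these libraries' means and spread over 10005 genes. Of genes given a log2 change of 1, 2 or 3, 71.6, 92.5 and 98.5% were recovered, 8 of 183 calls were false, and with no change 0 genes were called. The simulated noise was drawn independently for each gene, whereas genes vary together in the real libraries, so these rates need not hold for them. A split of the real libraries that mixes altitudes gave up to 9 changed genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

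Before the data were examined, the groups, the main test, the 27 lists and the rule for named genes were fixed. The lists cover hypoxia response, glycolysis and glycogen, oxidative phosphorylation, the mitochondrial genome, citrate cycle, fatty acid uptake and oxidation, fatty acid synthesis, slow fibre, fast fibre, myogenic and regeneration genes, muscle atrophy and autophagy, interferon response, heat shock and unfolded protein, immediate early genes, circadian clock, antioxidant defence, DNA methylation machinery, insulin and growth signalling and ribosomal proteins, and markers of adipocytes, endothelium, smooth muscle and pericytes, fibroblasts and matrix, macrophages, lymphocytes, erythroid cells and Schwann cells. The rule named the 12 largest and 12 smallest log2 fold changes past the threshold with a symbol, groups that do not overlap and a mean FPKM of at least 5 in the higher group, filled to 5 per direction by unadjusted p, up to 4 members of each list by unadjusted p, and the 6 most abundant genes. The individual Schwann cell markers are not reported here, and their results are left out of the counts over alternatives. The alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at a mean FPKM of 5, rescaling each library to a common total, median-of-ratios scaling, quantile normalization, limma without trend, with a robust fit, with array weights or with the shared replicate numbers as a replicate block, Spearman's correlation, and leaving out each library in turn. A fit without the genes listed at 0 in a library and at an FPKM of 5 or more in another was added after the data were seen.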

Results

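Longissimus dorsi, the long muscle of the back, was profiled by RNA sequencing in 6 healthy female Tibetan pigs, a breed of the Tibetan highland. The high altitude group was 3 free-ranging animals at an average of 4000 m. The low altitude group was 3 animals kept at an average of 500 m on the Chengdu plain, under experimental conditions with daily feeding, whose line had lived in the lowland for several generations. Altitude, husbandry, place and the history of the line therefore differed together between the groups. The table lists FPKM, fragments scaled to gene length and to the mapped total of the library, for 25322 genes. Its FPKM total per library was 568916, 571855 and 526368 at high altitude and 506611, 508814 and 566907 at low altitude. Between 9278 and 10100 genes per library reached an FPKM of 1. FPKM keeps no read totals, so absolute depth is unknown. The spacing of low values gave relative depths of 1.12, 0.858 and 1.22 at high altitude and 0.965, 0.999 and 0.880 at low altitude.

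Transcripts of the mitochondrial genome, a glycolytic enzyme and a fast myosin light chain had the highest mean levels. ATP8 and ATP6, subunits of the mitochondrial ATP synthase, had the highest mean FPKM, 45769 ± 1086 (SD, n = 3) and 30555 ± 1803 at high altitude and 43409 ± 1513 and 24923 ± 1342 at low altitude. The genes overlap on the mitochondrial genome, so how their reads were divided is uncertain. They were followed by the glycolytic enzyme GAPDH (22479 ± 8849 at high and 18376 ± 1036 at low altitude), the cytochrome oxidase subunits COX3 and COX2, and MYL11, a myosin light chain of fast fibres (16717 ± 1798 and 15443 ± 973). Mitochondrial genes made up 30.2, 31.9 and 32.5% of the FPKM total in the high altitude libraries and 30.7, 29.7 and 25.2% in the low altitude libraries. ACTA1, the skeletal muscle actin, was listed at 0 in 4 libraries and at 34168 and 35618 in high altitude library 2 and low altitude library 3, so an exact 0 in this table can be a failed estimate.

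The libraries did not separate by altitude along their main axis of variation. The first principal component, with 31.5% of the variance, set high altitude library 1 (score 38.2) apart from the other 5 (−20.3 to 7.75), and the next, with 27.9%, separated the groups. High altitude library 1 had the highest score of slow fibre genes (mean log2(FPKM + 1) of 9.34, against 6.90 to 8.57 in the others) and the lowest of fibroblast and matrix genes (3.45, against 4.53 to 5.14) and of fatty acid synthesis genes (1.89, against 2.19 to 3.39). Pearson's correlation over 10005 genes averaged 0.960 ± 0.0105 (SD) in the 6 pairs within a group and 0.953 ± 0.00739 in the 9 pairs between groups. The difference of 0.00726 had a p of 0.1 in an exact permutation test over the 10 splits of the libraries, the smallest p this design allows.

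**Figure D1:**
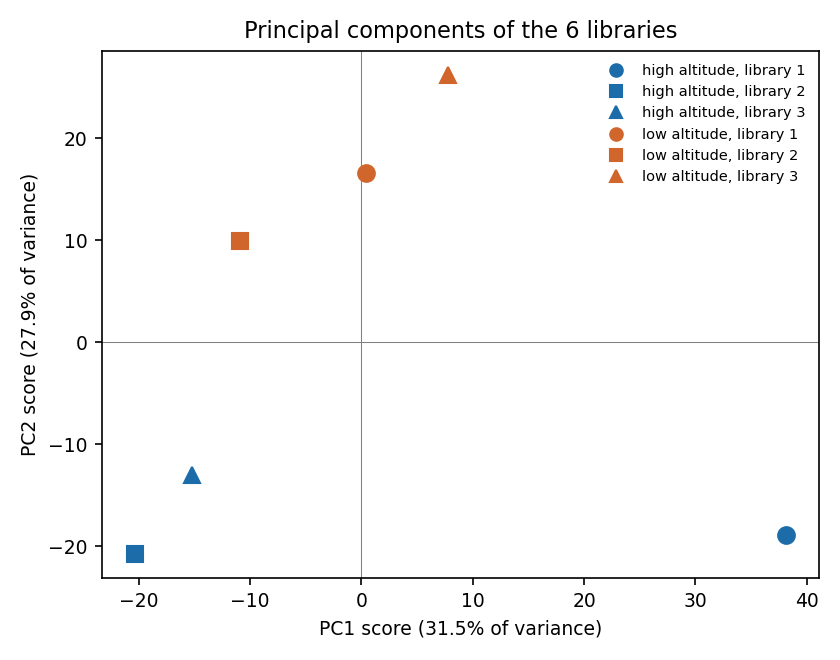
Scores of the 6 libraries on the first and second principal components of log2(FPKM + 1) over 10005 genes, with the share of variance on each axis (31.5% and 27.9%). Each point is 1 library, coloured by altitude, and high altitude library 1 lies at 38.2 on the first component, while the second runs from −20.8 to −13.0 at high altitude and from 9.90 to 26.2 at low altitude.

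The main comparison asked which genes differ in muscle between Tibetan pigs in the lowland and in the highland. PFKFB3, an early response gene and clock genes were among those higher at low altitude. PFKFB3, which makes the main activator of phosphofructokinase in glycolysis, was at an FPKM of 146 ± 83.5 (SD, n = 3) at low and 5.96 ± 4.99 at high altitude, 24.5-fold higher. PER1, a repressor of the circadian clock, was 8.49-fold higher (54.2 ± 12.4 against 6.38 ± 1.29). CRY2, another clock repressor, was 3.85-fold higher (42.8 ± 14.8 against 11.1 ± 0.955). NR4A2, an orphan nuclear receptor induced early by many stimuli, was 16.2-fold higher (9.33 ± 1.34 against 0.575 ± 0.120). S100A1, a calcium-binding protein of striated muscle, was 5.18-fold higher at high altitude (155 ± 40.1 against 30.0 ± 7.82).

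In limma with Benjamini-Hochberg adjustment, 23 of 10005 tested genes changed at an adjusted p under 0.05, 16 higher and 7 lower at low altitude, and all 23 by at least 2-fold. The fitted log2 fold change, low minus high on the log2(FPKM + 1) scale, which understates the change of low genes, was 2.89 for PER1 (SE 0.21, limma with Benjamini-Hochberg adjusted p = 0.00591) and 2.71 for NR4A2 (SE 0.15, adjusted p = 0.00132). It was 4.50 for PFKFB3 (SE 0.57, limma, Benjamini-Hochberg adjusted p = 0.0485) and 1.81 for CRY2 (SE 0.24, adjusted p = 0.0485). The zinc finger factor KLF10 rose from 0.783 ± 0.270 to 6.24 ± 0.615 FPKM (log2 fold change 2.03, limma, Benjamini-Hochberg adjusted p = 0.00667), and KIAA0408 from 3.22 ± 0.0965 to 10.7 ± 0.573 (1.47, adjusted p = 0.00741). WBP1L (5.40 ± 0.516 against 14.8 ± 2.09, adjusted p = 0.0396) and the hyaluronidase HYAL2 (4.52 ± 0.828 against 12.4 ± 0.771, adjusted p = 0.0463) were also higher at low altitude in this test with limma and Benjamini-Hochberg adjustment. S100A1 (log2 fold change −2.33, SE 0.27, adjusted p = 0.0396) and the transcription factor ATF5 (10.2 ± 0.565 against 4.35 ± 0.603, −1.08, adjusted p = 0.0485) were lower in the same limma test with Benjamini-Hochberg adjustment. FCN2, a lectin of the complement system, fell from 3.51 ± 0.673 to 0.502 ± 0.294 FPKM (limma, Benjamini-Hochberg adjusted p = 0.0396). It lay below the FPKM of 5 set for naming and was named after its values were seen. The other 12 changed genes have no symbol in the gene table used, 8 of them higher and 4 lower. Of the 4, 3 were listed at 0 in all 3 low altitude libraries, and no fold is given for them.

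Only 2 genes that were lower at low altitude met the naming rule, so 3 more were taken by their unadjusted p, and none of these passed the threshold. PLIN5, which coats lipid droplets in oxidative tissue, was at 6.49 ± 0.140 at high and 2.42 ± 0.638 FPKM at low altitude (log2 fold change −1.15, limma, Benjamini-Hochberg adjusted p = 0.0732). CACNG6, a subunit of the muscle calcium channel, was at 16.5 ± 0.655 and 8.44 ± 0.989 (−0.89, adjusted p = 0.0882), and HTATIP2 at 11.2 ± 2.34 and 4.45 ± 0.992 (−1.16, adjusted p = 0.115) in the same limma test with Benjamini-Hochberg adjustment. With array weights all 3 passed (0.0477, 0.0416 and 0.0477). The groups did not overlap in 1610 of the tested genes, 16.1%, where chance gives 10%, and 942 genes had an unadjusted p under 0.05. A split that mixes altitudes, high altitude library 1 with low altitude libraries 1 and 3, gave more on both measures, 1804 and 1071 genes, so these totals do not set altitude apart. The count of changed genes was 11 without high altitude library 2, 4 without high altitude library 3, 6 without low altitude library 1 and 4 without low altitude library 3. It was 6 with no filter on low values, 9 with median-of-ratios scaling, 10 with quantile normalization and 38 with limma's array weights. With median-of-ratios scaling PFKFB3, CRY2, WBP1L, S100A1 and ATF5 did not pass (limma, Benjamini-Hochberg adjusted p of 0.0535 to 0.0731), nor did these 5 with quantile normalization (0.0510 to 0.0763). With no filter the same 5 and HYAL2 did not pass (0.122 to 0.159), and with the shared replicate numbers as a replicate block those 6 did not pass (0.0813 to 0.115). PFKFB3, CRY2 and ATF5 did not pass with a pseudocount of 0.1 (0.0652, 0.0583 and 0.0583), PFKFB3 with a robust fit (0.0567) and ATF5 with the libraries rescaled to a common total (0.0870). Rescaling each library to a common total gave 24 higher and 6 lower genes with a median log2 fold change of 0.11 over all genes, against 0.041 in the deposited values. NR4A2 and PER1 passed the threshold in each of the 6 fits that left out 1 library. KLF10 passed in 4 of them, with a Benjamini-Hochberg adjusted p from limma of 0.0518 without high altitude library 3 and 0.0601 without low altitude library 3. KIAA0408 passed in 3, with 0.0588 and 0.0662 without the same libraries and 0.0762 without low altitude library 1. PFKFB3 passed only without high altitude library 2, WBP1L only without low altitude library 2 and HYAL2 only without high altitude library 1, while CRY2, S100A1 and ATF5 passed in none.

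**Figure D2:**
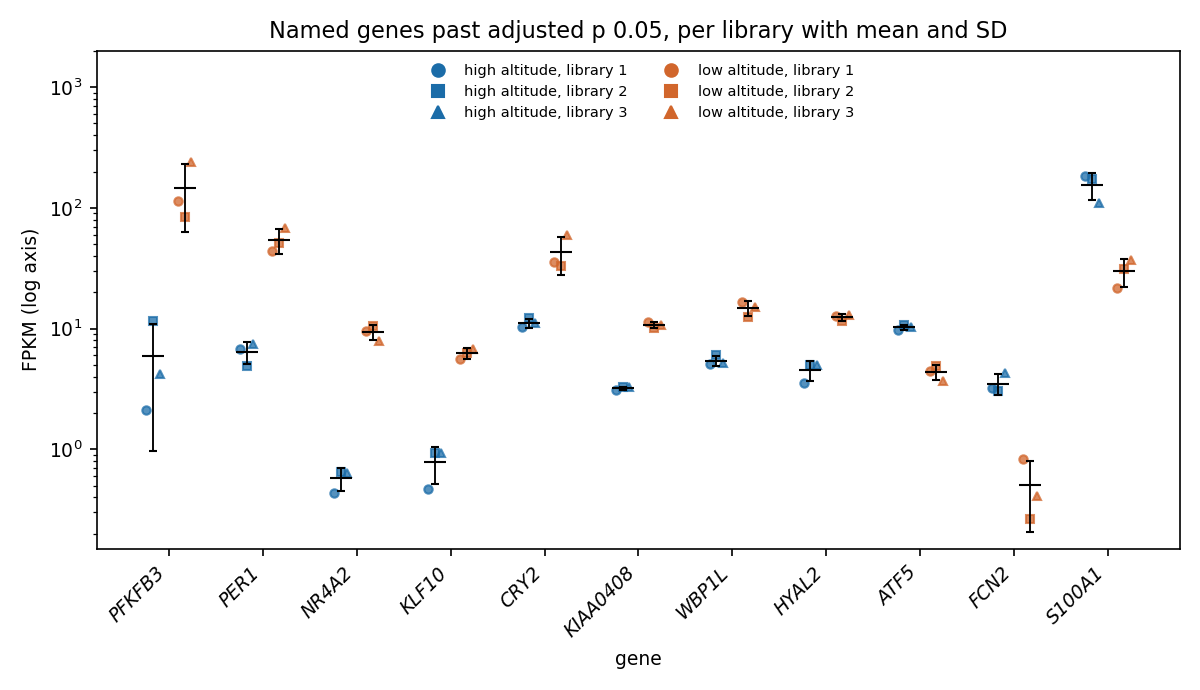
FPKM on a log axis of the 11 named genes past the adjusted p of 0.05, in each of the 3 high altitude (blue) and 3 low altitude (orange) libraries, with black bars for the group mean and SD. No gene's groups overlap, and PFKFB3 lies at 2.11 to 11.6 at high altitude and 84.0 to 241 at low altitude.

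Beyond single genes, 27 lists fixed beforehand were read, and 25 had enough tested members for a set test. By limma's camera with a preset correlation of 0.01, 11 lists changed against all other genes, 3 higher and 8 lower at low altitude. With the correlation estimated from the data 0 of the 11 passed. By fry, which asks whether a list's genes move on balance 1 way and compares them with no other genes, 2 of the 25 passed, immediate early genes, which are among the 11, and the circadian clock, which is not. A list called higher or lower below therefore passed camera with the preset correlation and not with an estimated one, and its p with an estimated correlation is given.

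Immediate early genes, transcription factors and signalling genes induced within minutes of a stimulus, were higher as a list at low altitude with the preset correlation but not with an estimated one. All 15 tested members had estimates above 0. Over all genes 1 member passed, NR4A2, and 8 members passed when adjusted over the list alone. The growth factor-induced matrix protein CCN1 was at 5.07 ± 2.38 at high and 39.7 ± 19.3 FPKM at low altitude, FOS at 9.27 ± 7.40 and 51.6 ± 13.3, and MYC at 2.66 ± 0.0510 and 5.15 ± 0.796. Over all genes none of these 3 passed (limma, Benjamini-Hochberg adjusted p = 0.0746, 0.147 and 0.155). CCN1 passed with rescaling to a common total, array weights and the replicate block (0.0275, 0.0291 and 0.0110), and FOS with array weights (0.0264) and without high altitude library 1 (log2 fold change 3.11, adjusted p = 0.0187). Immediate early genes moved by a mean log2 of 1.10 relative to other genes (camera in limma, Benjamini-Hochberg adjusted p = 9.57e-10; adjusted p = 0.0529 with an estimated correlation). Tested against no change rather than against other genes, the list passed fry (adjusted p = 0.000405). Its mean log2 level was 2.24 to 2.51 at high and 3.45 to 3.55 at low altitude.

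Of the 11 tested circadian clock genes, PER1 and CRY2 rose and no member fell over all genes tested. Adjusted over the list alone, 3 were higher and 1 was lower. NR1D2, a nuclear receptor that represses clock genes, was at 15.0 ± 2.36 at high and 24.0 ± 2.35 FPKM at low altitude, and BMAL1, the activator that drives PER and CRY genes, at 4.55 ± 0.495 and 2.27 ± 0.200 (limma, Benjamini-Hochberg adjusted p over all genes = 0.287 and 0.122; BMAL1 passed with array weights, 0.0477). With members on both sides the list did not pass camera (limma, Benjamini-Hochberg adjusted p = 0.306; adjusted p = 0.678 with an estimated correlation), while it passed fry (adjusted p = 0.0206). It passed camera where genes were filtered at a mean FPKM of 5 (1.09, limma, Benjamini-Hochberg adjusted p = 7.73e-05). That filter removed BMAL1, CRY1, CLOCK and BHLHE41, with estimates below 0 (−0.76, −0.36, −0.46 and −0.16), and PER2 and HLF, with estimates above 0. It kept PER1, CRY2 and NR1D2 above 0 and NFIL3 below 0 (−0.17). The pass therefore belongs to a shorter list that had lost members on the lower side.

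Genes of muscle atrophy and autophagy rose as a list at low altitude, with 12 of 15 tested members above 0, none past the threshold over all genes and 7 higher when adjusted over the list alone. FBXO32 and TRIM63, the ubiquitin ligases that mark muscle proteins for breakdown, were at 11.1 ± 3.35 and 59.2 ± 26.7 FPKM at high and at 52.7 ± 24.7 and 244 ± 144 at low altitude. FBXO32 passed without low altitude library 2 (log2 fold change 2.50, limma, Benjamini-Hochberg adjusted p = 0.0482). FOXO3, a transcription factor that drives both, was at 4.51 ± 1.01 and 11.4 ± 3.54, and SESN1, a stress-induced inhibitor of growth signalling, at 29.6 ± 3.52 and 68.1 ± 19.6. Relative to other genes the atrophy list moved by a mean log2 of 0.66 (camera in limma, Benjamini-Hochberg adjusted p = 2.17e-05; adjusted p = 0.535 with an estimated correlation). In insulin and growth signalling 0 of 15 genes passed over all genes, and 2 higher and 1 lower passed when adjusted over the list alone. These were the insulin receptor substrate IRS1 (14.5 ± 3.30 at high and 28.3 ± 0.793 at low altitude), TBC1D4, which holds back glucose transporters (5.27 ± 1.00 and 8.95 ± 1.60), and the mitochondrial deacetylase SIRT3 (4.97 ± 0.665 and 3.14 ± 0.263). The list did not pass (camera in limma, Benjamini-Hochberg adjusted p = 0.629). Of 11 myogenic and regeneration genes, 2 were higher adjusted over the list alone, MYF6, a muscle regulatory factor (49.9 ± 1.39 and 224 ± 97.4 FPKM), and MYH8, the perinatal myosin (1558 ± 123 and 2639 ± 363), whose reads can be shared with neighbouring myosin genes. Over all genes neither passed (limma, Benjamini-Hochberg adjusted p = 0.0585 and 0.164), and nor did the list (camera adjusted p = 0.420). MYF6 passed with rescaling to a common total, a robust fit and array weights (0.0130, 0.0475 and 0.0472).

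Nuclear oxidative phosphorylation genes and genes of the mitochondrial genome were lower as lists at low altitude, by small amounts per gene, and neither list passed with an estimated correlation. Of 42 nuclear oxidative phosphorylation genes 41 had estimates below 0, among them NDUFA8 of complex I (175 ± 39.8 at high and 96.4 ± 22.8 FPKM at low altitude) and UQCRC1 of complex III (200 ± 31.6 and 148 ± 30.1). So did all 13 genes of the mitochondrial genome, such as ND5 (3045 ± 150 and 2304 ± 113) and COX1. None of the 42 or the 13 passed over all genes or adjusted over the list alone. The lists moved by a mean log2 of −0.33 and −0.30 relative to other genes (camera in limma, Benjamini-Hochberg adjusted p = 6.49e-09 and 7.50e-08; adjusted p = 0.678 and 0.535 with an estimated correlation). The groups' mean levels of the mitochondrial genome did not overlap (13.09 to 13.21 against 12.82 to 12.95), whereas those of oxidative phosphorylation did. Without high altitude library 1, which had the highest level, oxidative phosphorylation moved by −0.14 and did not pass (limma's camera, Benjamini-Hochberg adjusted p = 0.0528). With quantile normalization the mitochondrial genome moved by −0.10 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.0739).

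Citrate cycle genes were lower as a list, with 14 of 18 estimates below 0 and none past the threshold over all genes or adjusted over the list alone. PDHB of pyruvate dehydrogenase was at 92.7 ± 6.86 FPKM at high and 72.9 ± 9.66 at low altitude, and DLD, shared by pyruvate and 2-oxoglutarate dehydrogenase, at 93.7 ± 17.4 and 69.8 ± 11.5. Glycolysis and glycogen genes were lower as a list, with 21 of 27 estimates below 0, and 1 passed adjusted over the list alone, PPP1R3C, which targets phosphatase to glycogen (10.6 ± 3.10 and 3.66 ± 1.04). Hexokinase HK2 was at 9.25 ± 4.38 and 5.0 ± 1.77, with 14.3 in high altitude library 1 and 6.69 and 6.75 in libraries 2 and 3 of that group. These lists moved by a mean log2 of −0.21 and −0.24 relative to other genes (camera in limma, Benjamini-Hochberg adjusted p = 0.00644 and 0.00134; adjusted p = 0.678 for each with an estimated correlation). The citrate cycle did not pass without high altitude library 1 (−0.056, camera in limma, Benjamini-Hochberg adjusted p = 0.621), without low altitude library 3 (−0.13, adjusted p = 0.105) or with array weights (adjusted p = 0.129), and it moved by −0.32 without high altitude library 3 (adjusted p = 8.30e-05). Glycolysis did not pass with quantile normalization (camera in limma, Benjamini-Hochberg adjusted p = 0.101).

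Fatty acid synthesis genes were lower as a list at low altitude, with 12 of 14 estimates below 0 and none past the threshold over all genes or adjusted over the list alone. ACLY, which supplies cytosolic acetyl-CoA, was at 1.59, 21.0 and 14.8 FPKM in the high altitude libraries and at 2.30, 3.39 and 3.65 at low altitude, and passed without high altitude library 1 (log2 fold change −2.19, limma, Benjamini-Hochberg adjusted p = 0.0333). The rate-limiting carboxylase ACACA was at 2.63 ± 1.47 and 1.25 ± 0.359. Its mean log2 move relative to other genes was −0.52 (camera in limma, Benjamini-Hochberg adjusted p = 0.00380; adjusted p = 0.678 with an estimated correlation). It was −0.95 without high altitude library 1, −0.29 without library 2 and −0.33 without library 3 of that group. Adipocyte markers, with 8 of 10 estimates below 0, moved by −0.41 and did not pass (camera in limma, Benjamini-Hochberg adjusted p = 0.0677), but did without high altitude library 1 (−0.79, adjusted p = 0.000253) and without low altitude library 3 (−0.59, adjusted p = 0.010). The move was −0.25 without high altitude library 2, −0.19 without high altitude library 3 and −0.16 without low altitude library 1. Adipocyte markers also passed with rescaling to a common total (0.0217), array weights (0.00436), the replicate block (0.00369) and without the genes listed at 0 in a library (0.0457). Of 28 genes of fatty acid uptake and oxidation, 1 was lower adjusted over the list alone, PLIN5, and 0 passed over all genes. PDK4, which shuts off pyruvate dehydrogenase, was at 22.9, 0.722 and 48.3 FPKM in the high altitude libraries and at 321, 130 and 527 in the low altitude libraries. It did not pass the threshold (log2 fold change 4.47, SE 1.19, limma, Benjamini-Hochberg adjusted p = 0.313). UCP3, a mitochondrial carrier, was at 14.4 ± 10.3 and 39.1 ± 27.2. The list's mean relative to other genes was 0.11 while its median log2 fold change was −0.025 and camera in limma gave the direction lower (Benjamini-Hochberg adjusted p = 0.265). It passed without high altitude library 2 (−0.028, adjusted p = 0.0423).

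Slow fibre genes were lower as a list, with all 7 estimates below 0, and none passed over all genes or adjusted over the list alone. Of the 16 slow fibre symbols only these 7 matched a listed gene, and the slow myosin MYH7 was not among them. The light chain MYL3 was at 1037 ± 359 FPKM at high and 527 ± 127 at low altitude and the slow troponin TNNI1 at 1342 ± 800 and 709 ± 150. Slow fibre genes moved by a mean log2 of −0.77 relative to other genes (camera in limma, Benjamini-Hochberg adjusted p = 0.00249; adjusted p = 0.678 with an estimated correlation). The move was −0.16 without high altitude library 1 (adjusted p = 0.561) and −1.46 without high altitude library 2. With array weights the list did not pass (adjusted p = 0.184). Of 15 fast fibre symbols 9 matched and were tested, without the fast myosins MYH1, MYH2 and MYH4, so fibre type was not read from these myosins. Of the 9 fast fibre genes 5 had estimates above 0 and none passed. MYBPC2, a fast myosin-binding protein, was at 1166 ± 150 and 1556 ± 91.1, and MYL1 at 11147 ± 722 and 10269 ± 285 (log2 fold change −0.12, but 0.095 with quantile normalization). Its median log2 fold change was 0.038 and its mean relative to other genes −0.16 (camera in limma, Benjamini-Hochberg adjusted p = 0.775), which was 0.030 with quantile normalization.

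**Figure D3:**
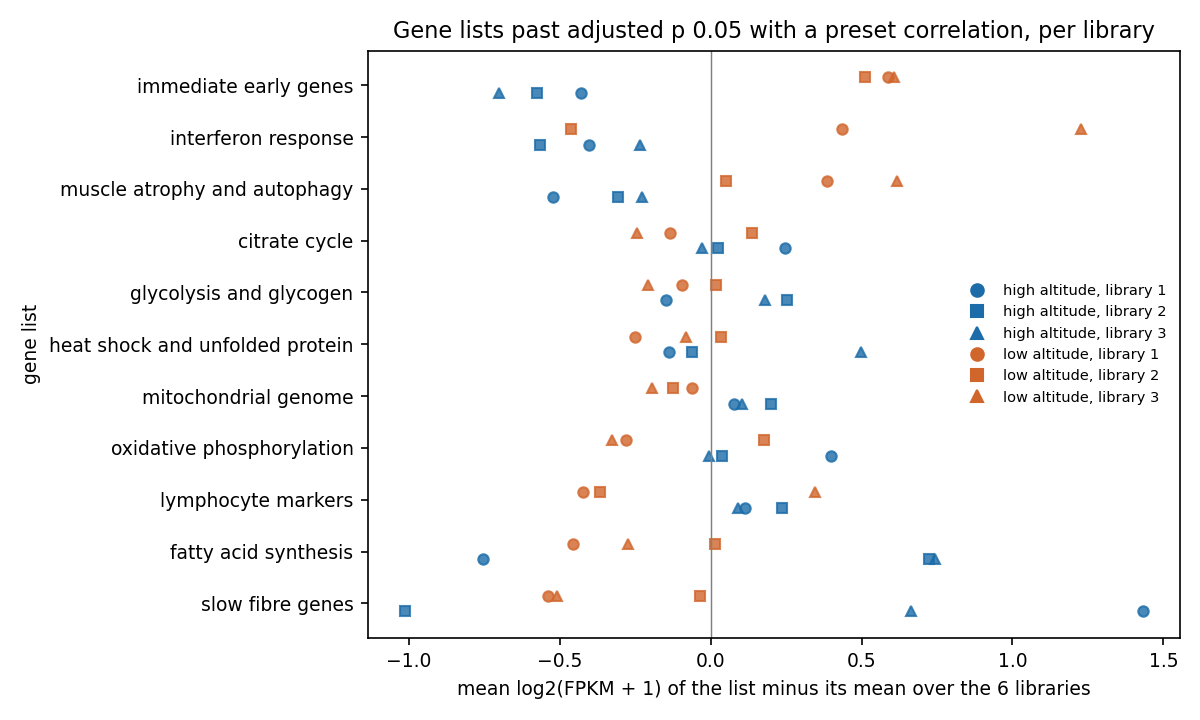
Mean log2(FPKM + 1) of the tested members of each of the 11 lists past the adjusted p of 0.05 with a preset correlation, minus the list's mean over the 6 libraries, with 1 point per library (blue high altitude, orange low altitude). The groups do not overlap for immediate early genes, muscle atrophy and autophagy and the mitochondrial genome, and overlap for the other 8 lists.

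Interferon response genes were higher as a list at low altitude. All 19 tested members had estimates above 0, none passed over all genes and 4 passed adjusted over the list alone. The antiviral GTPase MX2 was at 0.604 ± 0.407 FPKM at high and 8.16 ± 4.86 at low altitude, the RNA sensor RIGI at 0.772 ± 0.315 and 3.06 ± 1.30, and OAS2 at 2.27 ± 0.312 and 9.54 ± 6.18. MX2 passed without low altitude library 2 (log2 fold change 2.86, limma, Benjamini-Hochberg adjusted p = 0.0418). The interferon list moved by a mean log2 of 0.76 relative to other genes (camera in limma, Benjamini-Hochberg adjusted p = 1.23e-05; adjusted p = 0.678 with an estimated correlation). Its level was 1.72 to 2.06 at high altitude and 2.72, 1.83 and 3.52 in low altitude libraries 1, 2 and 3. Low altitude library 3 also had the highest levels of macrophage markers (3.26, against 2.30 to 2.74 in the others) and lymphocyte markers (1.96, against 1.19 to 1.85). Low altitude library 1, with the next highest interferon level, had the lowest of both. The list moved by 1.21 without low altitude library 2, and it did not pass without low altitude library 3 (0.34, camera in limma, Benjamini-Hochberg adjusted p = 0.0698) or among genes with a mean FPKM of 5 (adjusted p = 0.169).

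The hypoxia list did not pass. Of 18 tested hypoxia response genes PFKFB3 rose, over all genes as well as adjusted over the list alone, and 17 did not pass. MXI1 was at 6.12 ± 0.585 FPKM at high and 9.12 ± 1.03 at low altitude, and the prolyl hydroxylase EGLN3 at 2.66 ± 0.851 and 1.33 ± 0.484. The list's mean relative to other genes was 0.099, its median log2 fold change −0.095 and camera's direction in limma lower (Benjamini-Hochberg adjusted p = 0.629). Among genes with a mean FPKM of 5 that mean was 0.29 (adjusted p = 0.603). EPAS1, which encodes a hypoxia-inducible factor and was named after its values were seen, was at 20.8 ± 3.69 at high and 24.8 ± 2.53 FPKM at low altitude (limma, Benjamini-Hochberg adjusted p = 0.695). Of 12 endothelial markers 0 passed (camera in limma, Benjamini-Hochberg adjusted p for the list = 0.613). The vascular growth factor receptors were at 6.88 ± 1.02 and 2.87 ± 1.62 FPKM (KDR) and at 6.94 ± 0.369 and 4.52 ± 0.831 (FLT1), and ROBO4 at 2.76 ± 0.579 and 4.74 ± 1.27. Of 18 antioxidant genes 0 passed, with catalase CAT at 57.7 ± 7.25 and 84.0 ± 21.9 (camera in limma, Benjamini-Hochberg adjusted p = 0.590). Of 9 genes of the DNA methylation machinery 8 had estimates above 0 and 1 was higher adjusted over the list alone, GADD45B, a factor linked to active demethylation and stress signalling (3.40 ± 0.736 and 12.5 ± 4.22), which passed over all genes without low altitude library 2 (log2 fold change 1.86, limma, Benjamini-Hochberg adjusted p = 0.0482). The methyltransferase DNMT1 was at 1.68 ± 0.316 and 2.12 ± 0.308. The list moved by 0.24 and did not pass (camera in limma, Benjamini-Hochberg adjusted p = 0.151), but did without high altitude library 3 (0.32, adjusted p = 0.0292), and it moved by 0.15 without high altitude library 1 (adjusted p = 0.647).

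Heat shock and unfolded protein genes were lower as a list at low altitude, with 11 of 17 estimates below 0 and none past the threshold over all genes or adjusted over the list alone. The cochaperone DNAJB1 was at 6.31 ± 0.450 FPKM at high and 4.74 ± 0.624 at low altitude, and HSPA1L, whose reads can be shared with near-identical copies, at 62.8, 109 and 198 and at 64.7, 72.2 and 61.9. Heat shock genes moved by a mean log2 of −0.24 relative to other genes (camera in limma, Benjamini-Hochberg adjusted p = 0.0415; adjusted p = 0.743 with an estimated correlation). It did not pass without high altitude library 3 (−0.10, adjusted p = 0.513), without low altitude library 1 (−0.18, adjusted p = 0.229), with no filter or with quantile normalization (limma's camera, Benjamini-Hochberg adjusted p = 0.111 and 0.0646).

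Markers of other cell types in the muscle did not move in a common direction. Lymphocyte markers were lower as a list at low altitude, with all 5 estimates below 0, 0 past the threshold over all genes and CD3D of the T cell receptor lower adjusted over the list alone (2.24 ± 0.505 and 1.04 ± 0.0439 FPKM). Of the 19 lymphocyte symbols 15 matched a listed gene, and only these 5 were tested. CD3D, CD8A, PTPRC and CD2 lay between 0.669 and 4.45 FPKM in every library, close to the filter at 1. CD2 was at 1.96 ± 0.224 and 1.96 ± 1.63, with its highest value, 3.85, in low altitude library 3. Lymphocyte markers moved by a mean log2 of −0.34 (camera in limma, Benjamini-Hochberg adjusted p = 0.0195; adjusted p = 0.678 with an estimated correlation), and by −0.59 without low altitude library 3. They did not pass without high altitude library 1, low altitude library 1 or low altitude library 2 (−0.29, −0.22 and −0.21, adjusted p = 0.196, 0.172 and 0.201, camera in limma, Benjamini-Hochberg). Nor did they pass with quantile normalization or array weights (adjusted p = 0.0531 and 0.0791). Fibroblast and matrix genes had 17 of 20 estimates above 0, with POSTN at 2.65 ± 2.54 and 8.17 ± 3.71 and COL1A2 at 56.5 ± 38.5 and 91.3 ± 31.2, and moved by 0.40 without passing (camera in limma, Benjamini-Hochberg adjusted p = 0.0591). The move was 0.63 without high altitude library 2 (adjusted p = 0.00151), 0.58 without high altitude library 3 (adjusted p = 0.0212) and 0.56 without low altitude library 3 (adjusted p = 0.00422), and −0.0038 without high altitude library 1. It passed with median-of-ratios scaling (adjusted p = 0.0262), with quantile normalization (adjusted p = 0.0455), with no filter (adjusted p = 0.0248), at a mean FPKM of 5 (adjusted p = 0.0442) and with the replicate block (adjusted p = 0.0177).

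Macrophage markers, smooth muscle and pericyte markers and ribosomal protein genes did not pass camera in limma, with Benjamini-Hochberg adjusted p of 0.814, 0.819 and 0.498. None of their 8, 10 and 23 tested members passed over all genes or adjusted over the list alone. TYROBP of macrophages was at 17.1 ± 2.60 FPKM at high and 10.3 ± 4.51 at low altitude, CNN1 of smooth muscle at 15.0 ± 4.68 and 12.6 ± 1.08, and RPS13, a ribosomal protein, at 88.8 ± 4.86 and 109 ± 5.80. The median log2 fold change was 0.058 and the mean relative to other genes −0.089 in macrophage markers, and 0.036 and −0.046 in smooth muscle markers. Macrophage markers passed without low altitude library 3 (−0.39, camera in limma, Benjamini-Hochberg adjusted p = 0.00524), and ribosomal proteins passed without high altitude library 1 (0.19, adjusted p = 0.0213) and with array weights (0.17, adjusted p = 0.0311). Erythroid and Schwann cell markers had 2 tested members each, too few for a set test. HBB, a haemoglobin chain, was at 99.3 ± 54.2 and 77.6 ± 32.7 FPKM and HBM at 0.253, 1.31 and 3.11 in the high altitude libraries and 0.864, 1.37 and 0 in the low altitude libraries.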

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

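The fit without genes listed at 0 was the only alternative chosen after the data were seen. It gave 19 changed genes, all 19 among the 23. The counts of genes changed, and of genes changed at least 2-fold, were 23 each, and with the following alternatives they lay beyond 1.5 times that. They were 6 and 6 with no filter, where 17070 genes entered the adjustment, 9 and 9 with median-of-ratios scaling, 10 and 10 with quantile normalization, and 38 and 36 with array weights. The causes of these shifts were not tested. Leaving out 1 library gave 4 to 21 genes for both counts, with fewer samples in each fit. With pseudocounts of 0.1 and 0.5, a mean FPKM of 5, rescaling to a common total, no trend and a robust fit there were 16 to 30. Of the 11 lists 0 passed with an estimated correlation and 1 with fry, which also called the circadian clock, and the other alternatives called 8 to 13 lists. With median-of-ratios scaling and with quantile normalization PFKFB3, CRY2, WBP1L, S100A1 and ATF5 did not pass. The replicate numbers shared by the groups come from the titles, and the libraries are of separate animals. Same-numbered libraries had correlations of −0.015, 0.095 and −0.14 between their deviations from the group means, and those with different numbers −0.15 to 0.16. So few pairs show no pairing but cannot exclude a shared batch. With the replicate block 19 genes changed, 16 higher and 3 lower, and 11 of them were among the 23, and not every library correlated best with its own number. Relative depth ran from 0.858 to 1.22, and absolute depth, which sets how well low genes are measured, is unknown.

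With quantile normalization MYL1 turned to 0.095 and fast fibre genes to 0.030, and the cause was not tested. With 1 library left out, these turned sign and otherwise ran over the ranges given: CNN1 −0.41 to 0.011, HBB −0.63 to 0.12, CD2 −0.55 to 0.097, fibroblast and matrix genes −0.0038 to 0.63, fatty acid uptake and oxidation −0.028 to 0.19, fast fibre genes −0.35 to 0.069, smooth muscle and pericyte markers −0.17 to 0.055, ribosomal proteins −0.091 to 0.19 and macrophage markers −0.39 to 0.074. None of these had passed the threshold with all libraries, and fatty acid uptake and oxidation passed at −0.028, without high altitude library 2 (limma's camera, Benjamini-Hochberg adjusted p = 0.0423). Over the other alternatives, named genes kept direction and side of the threshold in 1252 results, lost it in 27 and gained it in 11, and lists in 254, 30 and 12. With 1 library left out these were 612, 38 and 6 for genes and 123, 10 and 8 for lists.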

Other observations

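Of the tests below, the glucocorticoid, contraction, single library and scaling tests were chosen or changed only after the results were seen. The splits, the time of day test and the test on genes listed at 0 were set beforehand.

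Between the adjusted p of 0.05 and 0.1 lay 13 further genes, 9 of them with a symbol, 7 higher and 2 lower at low altitude. None passed the threshold, and the 5 named here were chosen after their values were seen. KLF9, a zinc finger factor induced by glucocorticoids, was at 10.5 ± 3.58 (SD, n = 3) at high and 34.1 ± 5.64 FPKM at low altitude (log2 fold change 1.63, limma, Benjamini-Hochberg adjusted p = 0.0746), and KLF13 at 3.40 ± 0.742 and 8.65 ± 0.833 (1.14, adjusted p = 0.0746). ARRDC3, an arrestin-like protein, was at 7.89 ± 3.67 and 36.7 ± 6.51 (2.15, adjusted p = 0.0658), the deubiquitinase OTUD1 at 20.9 ± 9.89 and 86.9 ± 12.3 (2.10, adjusted p = 0.0959) and RASGEF1B at 1.95 ± 1.21 and 11.2 ± 2.66 (2.10, adjusted p = 0.0732) in the same limma test with Benjamini-Hochberg adjustment.

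The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The altitude split gave 23 changed genes, and the highest of the other 9 splits gave 9, so 1 split of 10 had a count as large, the real one. The counts of genes changed at least 2-fold were the same, 23 against 9, with 1 split as large. At an unadjusted p under 0.05 the altitude split gave 942 genes, and the split that set high altitude library 1 with low altitude libraries 1 and 3 gave 1071, with 1610 and 1804 genes whose groups do not overlap. For the lists, 2 splits of 10 gave 11 lists, the real one and the split that set high altitude library 1 with low altitude libraries 2 and 3, so the preset correlation called as many lists in a split that mixes altitudes.

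PER1 and CRY2 were higher at low altitude. Both were named by a rule that asks for groups without overlap, so leaving out 1 library could hardly halve their folds. With 1 library left out, their median absolute log2 fold change of 2.35 was 2.13 at its lowest. In both genes each low altitude library lay above each high altitude library, so no single library made the whole difference. Over 3 scalings the lowest was 2.30. The median-of-ratios factors ran only from 0.870 to 1.10, too near 1 to halve such folds, so these factors set the outcome of the scaling test. Factors this near 1 argue against scaling as the source of the 8.49-fold and 3.85-fold differences of PER1 and CRY2. These values concern the folds and not the call of CRY2, which passed in none of the 6 fits with 1 library left out. CRY2 also did not pass with median-of-ratios scaling (log2 fold change 1.76, SE 0.246, limma, Benjamini-Hochberg adjusted p = 0.0731) or quantile normalization (1.75, SE 0.244, adjusted p = 0.0763), against 1.81, SE 0.236 and 0.0485 with the deposited values. Nor did it pass with a pseudocount of 0.1 (0.0583), the replicate block (0.0863) or no filter (0.159). Over its 18 alternatives the adjusted p ran from 0.0125 to 0.218. The call lay close to the threshold, and under these scalings its fold and SE moved little. Both tests were first run with NR4A2 included, where 2.71 became 2.62 and 2.68, and NR4A2 was then taken out because it is no clock gene. A candidate explanation is the time of day at sampling. In clock genes other than PER1, CRY2 and BMAL1, the mean log2 level of the arm activated with PER1 minus that of the opposite arm differed by 0.59 between the groups, without overlap and 2.08 times the pooled SD of 0.283, just past the 2 set beforehand. The arms held only 4 and 3 genes, and the nearest libraries were at 0.20 (high altitude 1) and 0.30 (low altitude 2). BHLHE41 of the first arm went the other way (−0.16). None of the 7 passed over all genes (limma, Benjamini-Hochberg adjusted p of 0.287 to 0.878). Against 10000 random lists the arms stood at percentiles of 88.7 and 1.91, so the first was within the range of chance. Altitude, light, feeding, husbandry and line history stay open as untested.

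Immediate early genes were higher as a list at low altitude by camera with the preset correlation, and not with an estimated one. Its mean level was 3.45 to 3.55 in the low and 2.24 to 2.51 in the high altitude libraries, so no single library made the whole difference. With 1 library left out the list's move of 1.10 was 0.97 at its lowest. Levels so far apart could hardly have halved, so that test adds little. A glucocorticoid response to handling may account for it, and muscle contraction before sampling was also tried. The mean level of 8 glucocorticoid-responsive genes outside the list was higher by 1.27 (pooled SD 0.489). That of 4 contraction-responsive genes outside it was higher by 0.65 (pooled SD 0.178), and neither mean overlapped between the groups. Against 10000 random lists these 2 differences stood at percentiles of 100 and 99.5, but both lists had been changed after results were seen. Single genes of the 8 did overlap, FKBP5 (26.9, 8.26 and 10.3 FPKM at high, 22.4, 10.7 and 33.8 at low altitude) and ANGPTL4. None of the 12 passed over all genes (limma, Benjamini-Hochberg adjusted p of 0.152 to 0.803). PDK4 gave much of the first, which was 0.81 (pooled SD 0.302) over the 7 others, and MAFF and CSRNP1 of the second, which was 0.28 (pooled SD 0.125) without MAFF and 0.43 (pooled SD 0.174) without CSRNP1, each without overlap. Both were first run with the list's own members included, with differences of 1.29 over 9 genes and 1.03 over 10, and were repeated without them because shared members, 6 of the 10 for contraction, cannot test the pattern they belong to. Of the 4 remaining, MAFF and CSRNP1 had log2 fold changes of 1.76 and 1.32, PPARGC1A 0.26 and HK2 −0.74. HK2 ran from −0.94 to −0.41 with 1 library left out. The contraction difference thus rested on MAFF and CSRNP1, with the other genes on both sides of 0, so it cannot decide on contraction. Of the 8, SESN1 and FOXO1 are also in the atrophy list. These tests do not separate handling, contraction, feeding, line history, altitude and husbandry.

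Among the changed genes, 3 without a symbol were at 0 in all 3 low altitude libraries and at an FPKM of at least 1 in all 3 high altitude libraries. Counted over all genes, changed or not, and with either group at 0, the altitude split gave these 3 and no other. The split of high altitude library 1 with low altitude libraries 2 and 3 gave 5 on the same count, 4 of them at 0 in 1 group and 1 in the other. Of these 5, 3 were among that split's changed genes, and the highest number over the other 9 splits was 4. Estimates that failed at random may therefore account for the 3. A true absence at low altitude stays open, as no value in the table tells a failed estimate from an absent transcript.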
